A study of Cyprinus carpio with 9 samples.

How the data were processed

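Liver messenger RNA of common carp was measured in 9 libraries, 3 for each of 3 diets (earthworm, earthworm with duckweed at 1:1, and duckweed). Per the labels' protocols, fish of 492.6 ± 30 g were divided into groups of 90, fasted for 24 h and anaesthetised with MS-222, a fish anaesthetic, before the livers were frozen, and total RNA was extracted with Trizol. Per the labels, diet and replicate number come from the sample titles and descriptions. The labels give 3 samples per diet, while the series' design text speaks of duplicates.

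Per the file headers, each deposited file gives an FPKM value per gene ID. Counting with HTSeq 0.6.0 is listed, per the submitters' processing notes. The aligner, genome build and annotation are not given in the sources used here, and neither is the strand of the kit, so reads shared between near-identical copies, overlapping genes or antisense genes cannot be told apart. Carp has many duplicated genes, and such pairs are uncertain here. The sum of FPKM is not fixed, and the FPKM of a gene depends on what share of reads other genes take.

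The low FPKM values step in whole multiples of what 1 read is worth in a gene. From these steps each library's total and each gene's length were recovered, with lengths searched from 60 to 40000 bases. A length was found for 42996 genes, with a median of 1943 bases. Lengths were chosen to give whole reads within a tolerance of 0.02 reads. That 99.999% of the values above 0 came out as whole reads follows from this choice and is no check of it. The recovered reads of a library summed to 99.7% or more of its total. On simulated reads, 4 of 4 totals and 94.11% of genes with reads in every library were recovered exactly. The totals were 9915585, 10905342 and 11630872 reads for earthworm libraries 1 to 3, 11350056, 10961886 and 10631569 for earthworm+duckweed libraries 1 to 3, and 11750093, 11883466 and 11163631 for duckweed libraries 1 to 3. A count of 0 allows up to 3 reads, between 0.252 and 0.303 CPM (reads scaled to the library's total). Intervals and floors cover counting error only. Pairs of libraries of one diet differed by more than sampling noise (chi-square per degree of freedom of at least 41.9), so no library was counted as a copy of another.

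The design fixed before the data were examined had assumed counts. The deposited FPKM values are not counts, so limma replaced the planned count test; edgeR and DESeq2 were not run. FPKM values were divided by scaling factors (trimmed mean of M values, 30% of ratios and 5% of levels trimmed, computed on the recovered reads) and analysed as log2(scaled FPKM + 1), a pseudocount of 1. Genes at 1 FPKM or more in at least 3 libraries were tested. limma 3.58.1 in R 4.3.3 fitted 1 mean per diet over all 9 libraries, with empirical Bayes moderation (trend and robust options), two-sided tests and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05. The factors ranged from 0.675 to 1.12 in 8 libraries and reached 2.44 in the library labelled earthworm+duckweed 3. The median log2 fold change of duckweed against earthworm was 0.04 after scaling and 0.15 in FPKM as deposited, and that of the mixed diet against earthworm was 0.003 and 0.33.

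The test was tried on simulated reads for the comparison of duckweed with earthworm, with the spread of the 8 libraries other than the one labelled earthworm+duckweed 3. In these, 200 genes with a mean of at least 50 reads were changed, so changes in genes with fewer reads were not tried. Over 19092 genes, 6% of genes changed 2-fold, 30% of those changed 4-fold, 72% of those changed 8-fold and 84% of those changed 16-fold were called, with 5 false calls. With the reads of the library labelled earthworm+duckweed 3 added as deposited, over 19590 genes, the shares were 0%, 4%, 48% and 62%, with 0 false calls. With a low dispersion of 0.05 in every gene, over 19225 genes, they were 24%, 100%, 98% and 100%.

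The rule for named genes, fixed before the data were examined, took genes past the adjusted threshold, and with no gene names at most 2 in each direction per comparison. No gene passed. The genes named were instead chosen after their values were seen: the 2 higher and the 2 lower with the smallest p in the limma fit without the library labelled earthworm+duckweed 3, among genes whose libraries of the groups compared did not overlap in that fit and whose mean was 1 FPKM or more. Other IDs in the text were also chosen after their values were seen. The 33 gene lists fixed before the data were examined, with 603 entries, and the planned removal of exocrine pancreas genes needed gene names and were not used.

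Alternatives were other scaling factors (median ratio), FPKM as deposited, no filter, a filter of 1 CPM in at least 3 libraries, limma-voom on the recovered reads, only the groups compared, the replicate number as a block, no robust option, and each library left out. A pseudocount of 0.1, weights per library and settings without the library labelled earthworm+duckweed 3 were chosen after seeing the data. Differences of shares were tested with exact permutation tests. Correlations, shares and figures were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.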

Results

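The data were messenger RNA profiles of the liver of adult common carp (Cyprinus carpio) given 1 of 3 foods. One group ate earthworm, an animal food, one ate duckweed, a small floating water plant, and one ate both in a ratio of 1:1. The question was how liver gene expression differs between an animal and a plant diet. Each diet had 3 libraries, 9 in all, and each library was a list of 42997 gene IDs with a value in FPKM (fragments per kilobase of gene model, divided by the library's total). The labels do not say whether a library came from 1 fish or from several, so the p-values below measure the spread between these libraries, which may in part be technical. The files do not pair the gene IDs with names, and 0 of the 42997 IDs matched the reference table of carp genes. Genes are therefore given by ID, and no pathway or cell type could be assessed. Totals ranged from 9915585 to 11883466 reads per library.

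In 8 of the 9 libraries a small set of genes took a large part of the reads. The 50 genes with the highest mean FPKM over those 8 libraries, a set chosen after the values were seen, held 45.4% ± 3.60 (SD, n = 3) of reads on earthworm and 36.0% ± 2.26 (SD, n = 3) on duckweed. Mixed-diet libraries 1 and 2 held 47.0% and 45.0%. The library labelled earthworm+duckweed 3 held 1.26% (exact 95% binomial interval 1.25 to 1.27%, counting error only). Its correlation with the other libraries across 21239 genes was 0.45 to 0.52, whereas the other 8 correlated with each other at 0.85 to 0.94. Genes are not independent replicates, so these correlations carry no p-value. Among the 8, libraries of the same diet correlated at 0.904 on average over 7 pairs, and libraries of different diets at 0.902 over 21 pairs. Counts are therefore given both with and without the library labelled earthworm+duckweed 3.

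**Figure D1:**
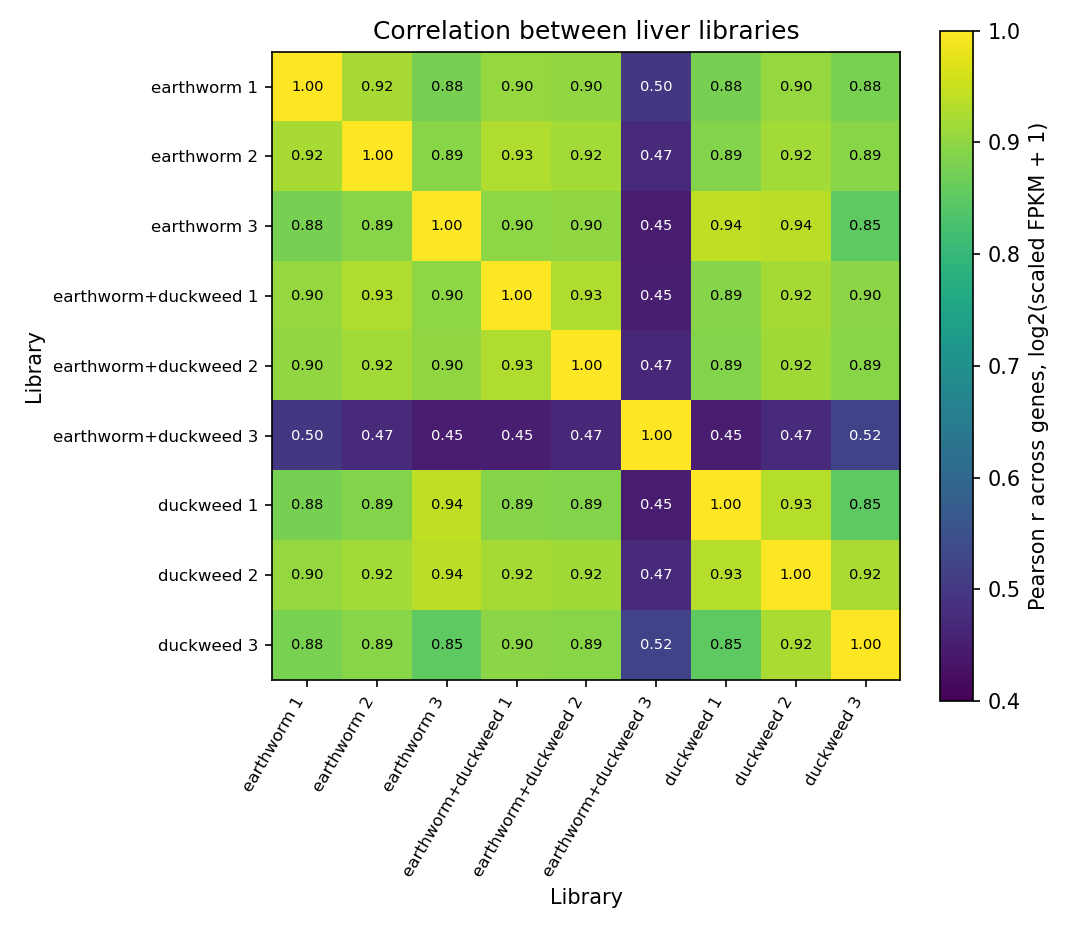
Pearson correlation between each pair of the 9 libraries, across genes, of log2(scaled FPKM + 1), with rows and columns as libraries and colour as the correlation. The library labelled earthworm+duckweed 3 lies at 0.45 to 0.52 with the others, which lie at 0.85 to 0.94 with each other.

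The comparison of duckweed with earthworm set the plant diet against the animal diet. Gene CAFS_CommonC_G_001218 averaged 253.5 ± 119 FPKM (SD, n = 3) on earthworm and 19.9 ± 8.51 FPKM (SD, n = 3) on duckweed. Gene CAFS_CommonC_G_045358 averaged 17.4 ± 16.2 FPKM (SD, n = 3) on earthworm and 0.84 ± 0.73 FPKM (SD, n = 3) on duckweed. In the other direction, CAFS_CommonC_G_047392 averaged 1.1 ± 1.01 FPKM (SD, n = 3) on earthworm and 57.3 ± 51.3 FPKM (SD, n = 3) on duckweed, and CAFS_CommonC_G_010892 averaged 0.19 ± 0.33 FPKM (SD, n = 3) and 2.80 ± 0.36 FPKM (SD, n = 3). These 4 genes were chosen so that the 3 libraries of one diet did not overlap the 3 of the other, and none passed the test after adjustment. Their log2 fold changes, in the same order, were -3.74 (SE 1.54), -3.28 (SE 0.49), 4.43 (SE 1.17) and 1.75 (SE 0.29), on the scale of log2(FPKM + 1), which understates the change of low genes. The adjusted p was 1 for each of the 4 (limma, 9 libraries, Benjamini-Hochberg) and 0.325 for each without the library labelled earthworm+duckweed 3.

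The share of reads in the 50 most abundant genes was 9.34 percentage points lower on duckweed than on earthworm. All 3 duckweed libraries lay below all 3 earthworm libraries, and the two-sided exact permutation test gave p = 0.1, the smallest value that 3 against 3 allows. The share held by each library's own 50 most abundant genes was 41.8% ± 2.5 (SD, n = 3) on duckweed and 48.5% ± 3.27 (SD, n = 3) on earthworm, again with exact permutation p = 0.1. Duckweed library 2 held 58 genes particular to duckweed library 3 at a median of 0.334 of their level there. Whether the 3 duckweed libraries are independent samples is therefore open, and with it the n, the SDs and the permutation p given for duckweed. After scaling, 14 of the 50 genes were lower in every duckweed library than in every earthworm library and 1 was higher (15 and 5 in FPKM as deposited). Chance gives 5% of genes in each direction for a set chosen without the values. The 50 were ranked over the 8 libraries, of which only the 3 on duckweed came from fish without earthworm. They held 41 to 43 of each earthworm library's own 50, but 37, 42 and 35 of those of duckweed libraries 1 to 3. The set may thus favour genes high with earthworm, so neither the 14 nor the 9.34 points comes from a neutral set. Over all 20105 genes tested in the 8 libraries, 784 were lower and 1021 higher in every duckweed library after scaling, against 1005 by chance in each direction, and 428 were lower and 1569 higher in FPKM as deposited.

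**Figure D2:**
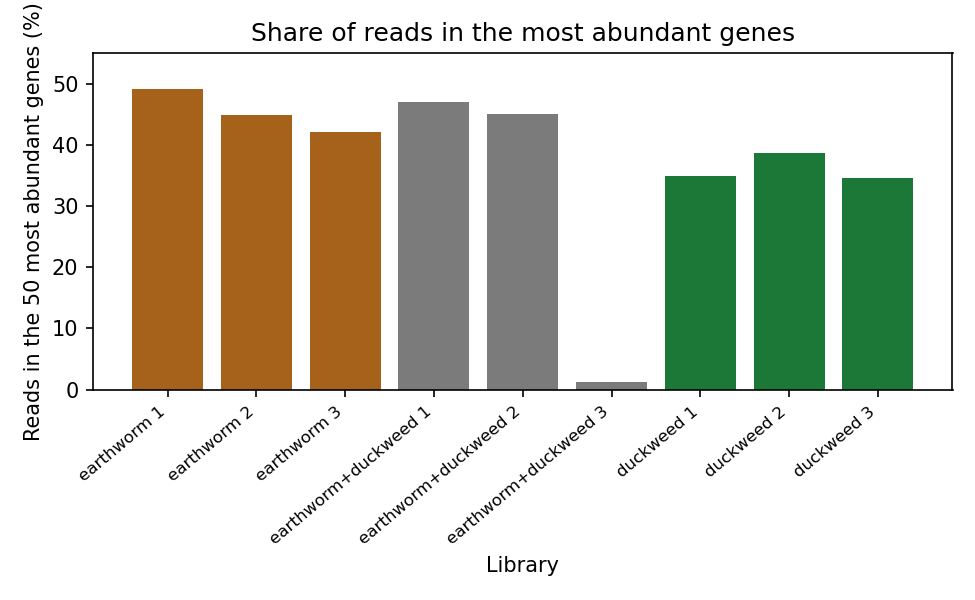
Percent of each library's reads in the 50 most abundant genes, 1 bar per library, coloured by diet. The duckweed bars lie between 34.6 and 38.6%, the earthworm bars between 42.1 and 49.2%, and the bar of the library labelled earthworm+duckweed 3 at 1.26%.

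Of 21239 genes tested with limma, 0 were past an adjusted p of 0.05 in either direction between duckweed and earthworm, and 545 had an unadjusted p under 0.05, where chance alone gives about 1062. limma-voom on the recovered reads also called 0, with 373 at an unadjusted p under 0.05. Without the library labelled earthworm+duckweed 3, 0 of 20105 genes passed and 962 had an unadjusted p under 0.05. Of the 545, 351 were higher and 194 lower on duckweed, and of the 962, 561 and 401. Fits of FPKM as deposited gave 348 such genes with 9 libraries, 271 higher and 77 lower, and 1086 with 8, 841 higher and 245 lower. The 545 became 309 without earthworm library 1, 357 without earthworm library 2, 838 without earthworm library 3 and 355 without duckweed library 2. Leaving out both the library labelled earthworm+duckweed 3 and earthworm library 3 gave 11 genes, 3 higher and 8 lower on duckweed, and 1595 at an unadjusted p under 0.05, a setting chosen after seeing the data.

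The comparison of the mixed diet with earthworm asked what the addition of duckweed changed. Gene CAFS_CommonC_G_047194 was at 51.2 and 43.3 FPKM in mixed-diet libraries 1 and 2, against 6.69 ± 0.79 FPKM (SD, n = 3) on earthworm. Gene CAFS_CommonC_G_090852 was at 611 and 2265 FPKM in those libraries, against 55.9 ± 12.8 FPKM (SD, n = 3). Lower values were found for CAFS_CommonC_G_045358, at 0.52 and 0.36 FPKM against 17.4 ± 16.2 FPKM (SD, n = 3), and for CAFS_CommonC_G_023925, at 0.50 and 2.46 FPKM against 11.8 ± 4.39 FPKM (SD, n = 3). The library labelled earthworm+duckweed 3 departed from this in CAFS_CommonC_G_090852, at 0.58 FPKM, and in CAFS_CommonC_G_023925, at 119.98 FPKM. The log2 fold change of CAFS_CommonC_G_090852 was 1.07 in the fit of 9 libraries but -0.21 without mixed-diet library 1 and -1.08 without mixed-diet library 2. None of the 4 passed the test. Their adjusted p lay between 0.59 and 0.982 (limma, 9 libraries), and was 0.65 for each without that library.

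Between the mixed diet and earthworm, limma called 0 of 21239 genes, with 667 at an unadjusted p under 0.05. limma-voom called 0, with 721. Without the library labelled earthworm+duckweed 3, limma called 0 of 20105 genes, with 1095 at an unadjusted p under 0.05. The 667 became 1417 without earthworm+duckweed library 1, above the 1053 given by chance, and 1014 without earthworm+duckweed library 2. Of the 667, 320 were higher and 347 lower on the mixed diet, and of the 1095, 585 and 510. In FPKM as deposited there were 595 such genes with 9 libraries, 456 higher and 139 lower, and 871 with 8, 362 higher and 509 lower. The share of reads in the 50 most abundant genes was 46.0% ± 1.42 (SD, n = 2) in mixed-diet libraries 1 and 2 and did not differ from that on earthworm by more than the spread (two-sided exact permutation p = 0.8). With earthworm+duckweed libraries 2 and 3 both left out, 1 gene was called lower.

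The comparison of duckweed with the mixed diet asked what the removal of earthworm from the mixture changed. Gene CAFS_CommonC_G_008056 averaged 56.0 ± 19.7 FPKM (SD, n = 3) on duckweed and was at 7.3 and 4.0 FPKM in mixed-diet libraries 1 and 2. Gene CAFS_CommonC_G_089847 averaged 172 ± 80.9 FPKM (SD, n = 3) on duckweed and was at 10.3 and 11.1 FPKM in the same mixed-diet libraries. Gene CAFS_CommonC_G_056542 averaged 1.82 ± 0.69 FPKM (SD, n = 3) on duckweed, against 25.6 and 15.4 FPKM. Gene CAFS_CommonC_G_054592 averaged 2.62 ± 0.81 FPKM (SD, n = 3), against 25.6 and 28.9 FPKM. The library labelled earthworm+duckweed 3 was outside the range of the other mixed-diet libraries in all 4 genes. It was at 70.3 FPKM for CAFS_CommonC_G_008056 and 21.3 FPKM for CAFS_CommonC_G_089847. It was at 0.19 FPKM for CAFS_CommonC_G_056542 and at 0 for CAFS_CommonC_G_054592 (a count of 0 allows up to 0.282 CPM), below every duckweed library. The log2 fold change of CAFS_CommonC_G_054592 was -1.53 in the fit of 9 libraries, but limma-voom on the reads of the same libraries turned it to 0.87. The adjusted p of the 4 genes lay between 0.795 and 0.975 with 9 libraries and between 0.141 and 0.323 without that library (limma).

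**Figure D3:**
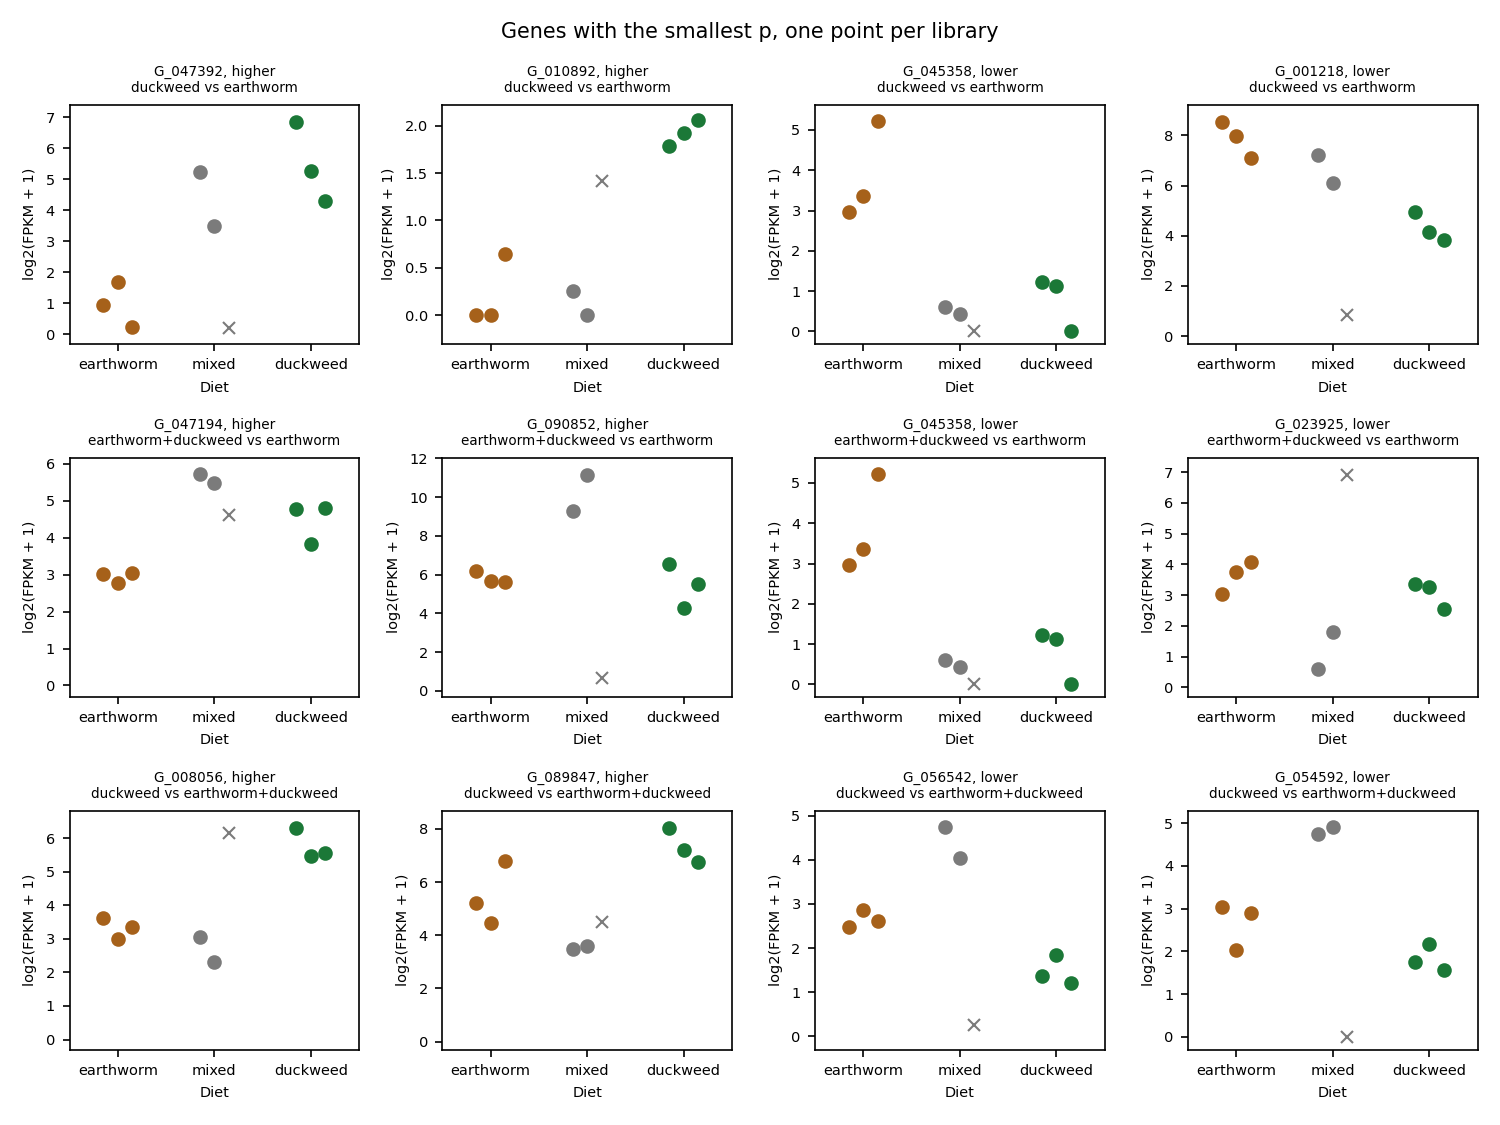
Values of the genes named for the 3 pairwise comparisons, as log2(FPKM + 1) by diet, with 1 point per library and a cross for the library labelled earthworm+duckweed 3. The genes were chosen so that the points of the diets compared do not overlap once the cross is set aside. For CAFS_CommonC_G_045358 these were 6.80 to 36.0 FPKM on earthworm and at most 1.35 FPKM on duckweed.

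Between duckweed and the mixed diet, limma called 0 of 21239 genes, with 946 at an unadjusted p under 0.05 (697 higher and 249 lower on duckweed), and limma-voom called 0, with 1060. Without the library labelled earthworm+duckweed 3, limma called 0 of 20105 genes, with 1316 at an unadjusted p under 0.05 (682 higher and 634 lower). In FPKM as deposited there were 1336 without that library, 1080 higher and 256 lower, so its evenness held only after scaling. The 946 became 1632 without earthworm+duckweed library 1 and 569 without duckweed library 2. The share of reads in the 50 most abundant genes was 9.96 percentage points lower on duckweed than in mixed-diet libraries 1 and 2. For each library's own 50 most abundant genes it was 7.18 points lower. The two-sided exact permutation p was 0.1 for each measure, the smallest that 3 against 2 allows. Array weights without the library labelled earthworm+duckweed 3, added after seeing the data, called 2 genes, CAFS_CommonC_G_056542 and CAFS_CommonC_G_054592, both lower on duckweed (adjusted p = 0.0402, limma), although the second turned direction with limma-voom on 9 libraries. Duckweed library 2 had the highest weight there, 4.39, and with it also left out the same weights called 0 genes (smallest adjusted p = 0.358, limma). A second estimate of those weights, which did not converge, called 373.

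The last contrast asked whether the mixed diet lay midway between the single diets on the log2 scale. Gene CAFS_CommonC_G_056542 was at 25.6 and 15.4 FPKM in mixed-diet libraries 1 and 2, above both the earthworm libraries, with 5.32 ± 0.85 FPKM (SD, n = 3), and the duckweed libraries, with 1.82 ± 0.69 FPKM (SD, n = 3). Gene CAFS_CommonC_G_054592 was at 25.6 and 28.9 FPKM, against 5.62 ± 2.2 FPKM (SD, n = 3) on earthworm and 2.62 ± 0.81 FPKM (SD, n = 3) on duckweed. In both genes the library labelled earthworm+duckweed 3 went the other way, at 0.19 FPKM and at 0, below every library of the single diets. Their log2 fold changes were 0.97 and 1.04 in the fit of 9 libraries, and limma-voom turned them to -0.66 and -1.45. Without mixed-diet library 1, that of CAFS_CommonC_G_056542 was -0.0048. Gene CAFS_CommonC_G_001333 was lower in mixed-diet libraries 1 and 2, at 12.4 and 12.1 FPKM, against 145 ± 50.6 FPKM (SD, n = 3) and 137 ± 86.0 FPKM (SD, n = 3). Gene CAFS_CommonC_G_023925 was at 0.50 and 2.46 FPKM, against 11.8 ± 4.39 FPKM (SD, n = 3) and 7.54 ± 2.36 FPKM (SD, n = 3). For the last 2 genes the library labelled earthworm+duckweed 3 was at 0 and at 119.98 FPKM, the latter above every library of the single diets. The log2 fold change of CAFS_CommonC_G_023925 turned from -0.68 to 0.34 without mixed-diet library 1. The adjusted p of the 4 genes lay between 0.907 and 0.932 with 9 libraries and between 0.229 and 0.56 without the library labelled earthworm+duckweed 3 (limma). limma called 0 of 21239 genes, with 970 at an unadjusted p under 0.05 (331 higher and 639 lower on the mixed diet), and limma-voom called 0, with 1112. Without the library labelled earthworm+duckweed 3, limma called 0 of 20105 genes, with 1294 at an unadjusted p under 0.05 (686 higher and 608 lower). In FPKM as deposited the balance went the other way, with 469 higher and 346 lower of 815 genes in 9 libraries and 308 higher and 800 lower of 1108 in 8, so no direction of the balance held across scalings. The 970 became 1939 without earthworm+duckweed library 1 and 617 without duckweed library 2, and the 1294 became 821 with earthworm+duckweed library 2 also left out. Leaving out earthworm+duckweed library 2 gave 1 call, CAFS_CommonC_G_040125, lower on the mixed diet (adjusted p = 0.0274, limma).

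The fold changes of duckweed against earthworm and of the mixed diet against earthworm correlated at 0.319 across 21239 genes, with a covariance of 0.0855. Both comparisons share the earthworm libraries, so unchanged groups would also correlate, and 100 simulations of that case averaged a correlation of 0.501 and a covariance of 0.175. The simulations gave every library the same spread per gene, pooled over the diets. With 9 libraries that spread took in the library labelled earthworm+duckweed 3. Observed values below the simulated ones can follow from an unequal spread, so no conclusion is drawn from them. Without the library labelled earthworm+duckweed 3 the correlation was 0.326 and the covariance 0.0652, against 0.449 and 0.0896 in the simulations. The observed covariance minus the simulated one was -0.0898 with 9 libraries and -0.0244 with 8. The observed correlation depended on single libraries, at 0.501 without earthworm library 3 and 0.208 without duckweed library 3. Simulations of those sets averaged 0.601 and 0.447. The covariance rose to 0.193 without earthworm library 3, and the covariance difference was -0.192 without earthworm library 1 and -0.166 without earthworm library 2. Over the 9 libraries left out in turn that difference lay between -0.192 and -0.0244. Each list of calls was empty, so there was no overlap to compare. Splitting the 3 earthworm libraries so that each part kept 2 was not possible.

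Differences between libraries of one diet were large. Of 1404 genes that reached 50 FPKM in at least 1 of the 8 libraries, 16 were below 0.5 FPKM in at least 2 of them. In 14 of the 16, libraries of the same diet lay on both sides of 0.5 FPKM. Few patterns of high and low libraries keep every diet on 1 side, so most such genes would split by chance as well. The other 2, CAFS_CommonC_G_063277 and CAFS_CommonC_G_030002, were on 1 side within each diet, the first below it in all 3 duckweed libraries and the second in mixed-diet libraries 1 and 2. Gene CAFS_CommonC_G_025752 was at 157.9 FPKM in duckweed library 1 and at 0.12 FPKM in duckweed library 2, and gene CAFS_CommonC_G_000269 was at 989 FPKM in earthworm library 1 and at 0.10 FPKM in earthworm library 2. The first principal component of the 8 libraries held 30.0% of the variance and set earthworm library 3 and duckweed library 1 (scores -57.4 and -58.9) against duckweed library 3 (score 59.5). Earthworm library 3 correlated at 0.942 and 0.938 with duckweed libraries 1 and 2, and at 0.876 and 0.893 with earthworm libraries 1 and 2. In all, 5 of the 8 libraries correlated best with a library of another diet. Among the 8, 7 pairs were within a diet and 21 between diets, so chance alone would give most libraries such a partner. Duckweed libraries 2 and 3 shared transcripts found little elsewhere. There were 58 genes at 10 FPKM or more in duckweed library 3 and at 4 or more times the highest of the 6 libraries other than these 2, and duckweed library 2 held them at a median of 0.334 of their level in duckweed library 3. The highest such number for any of the other 55 ordered pairs of libraries was 16.

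**Figure D4:**
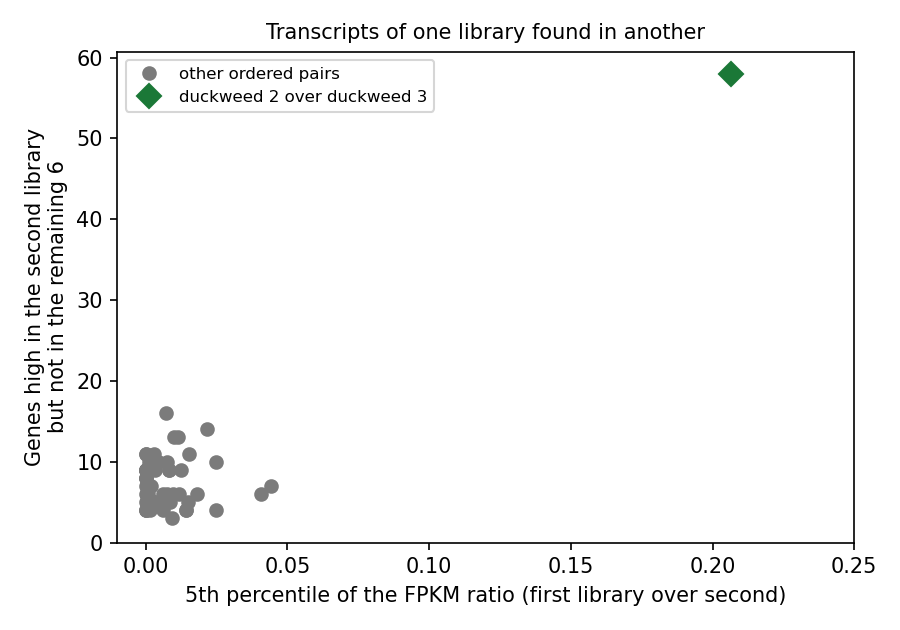
For each ordered pair of 8 libraries, the number of genes high in the second library but not in the remaining 6 (y axis) against the 5th percentile of the FPKM ratio of the first library to the second over those genes (x axis). The pair of duckweed library 2 over duckweed library 3 lies at 58 genes and 0.207, and no other pair is above 16 genes or 0.0441.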

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

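In all 4 comparisons, limma called 0 genes under the other scaling factors, FPKM as deposited, both other filters, limma-voom, a pseudocount of 0.1, the fit without the robust option and, where it applies, only the groups compared. Leaving out 1 library at a time gave 0 to 1 calls for the contrast of the mixed diet with the mean of the single diets (1 without earthworm+duckweed library 2) and 0 in the pairwise comparisons. The pseudocount and the further settings were chosen after seeing the data. With the library labelled earthworm+duckweed 3 and earthworm library 3 out, duckweed against earthworm gave 11 calls and duckweed against the mixed diet 2. With earthworm+duckweed libraries 2 and 3 out, 1 gene was called in each of the mixed diet against earthworm, duckweed against the mixed diet and the mixed-diet contrast; the lone mixed library is then assumed to vary like the other groups. Weights per library without the library labelled earthworm+duckweed 3 gave 2 calls for duckweed against the mixed diet, and by an estimate that did not converge 373 there and 24 for duckweed against earthworm. Duckweed library 2 took a weight of 4.39 and the other 7 libraries 0.445 to 1.1; with it also out, the first estimate called 0 genes. The cause of the other changes was not tested. Counts at an unadjusted p under 0.05 moved by over 1.5 times in some settings. For duckweed against earthworm, the mixed diet against earthworm, duckweed against the mixed diet and the mixed-diet contrast, they were 545, 667, 946 and 970, but 1014, 1266, 1538 and 1652 with no filter (42997 genes) and 1803, 1156, 2973 and 1961 with weights per library (1132, 1610, 2079 and 2139 by the estimate that did not converge). FPKM as deposited gave 348 for the first, and only the groups compared 855 and 444 for the first and second.

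The correlation of fold changes, 0.319, lay between 0.208 (duckweed library 3 out) and 0.501 (earthworm library 3 out) when each library was left out in turn. It was below the mean of its simulation, which assumed an equal spread in every library, in each case. With the replicate number as a block the correlation was 0.319, which a balanced block cannot change. In that fit 0 genes were called in each comparison. Of 9 same-numbered pairs, 0 correlated over 0.1 in their deviations (range -0.404 to 0.0768), and 1 of the 9 libraries correlated best with its own number. Every pair with a mixed-diet library, same-numbered or not, lay between -0.0941 and 0.0768, so those pairs told little. Same-numbered earthworm and duckweed libraries correlated at -0.205, -0.0933 and -0.404. With so few pairs, a batch shared by a replicate number was not excluded.

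Directions of 4 named genes turned. Without another mixed-diet library, the one labelled 3 makes up more of its group. Over the fits without 1 library, the log2 fold change of CAFS_CommonC_G_090852, mixed diet against earthworm, lay between -1.08 and 4.46 (-0.21 without mixed-diet library 1), and those of CAFS_CommonC_G_056542 and CAFS_CommonC_G_023925 for the mixed-diet contrast between -0.0048 and 2.46 and between -2.06 and 0.34. With limma-voom, CAFS_CommonC_G_054592 was at 0.87 for duckweed against the mixed diet and -1.45 for the mixed-diet contrast, and CAFS_CommonC_G_056542 at -0.66 for the latter. DESeq2 was not run, nor were the gene list tests and the exocrine pancreas settings. The simulations of duckweed against earthworm changed only genes with a mean of at least 50 reads. With all 9 libraries, 0% of those changed 2-fold, 4% of those changed 4-fold and 48% of those changed 8-fold were called. With 8 libraries the shares were 6%, 30% and 72%, so most changes of up to 4-fold were not detectable.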

Other observations

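The patterns below were found in the data and then tested on the same data. For the library that stands apart, the tests of totals, diet, swapped labels and trace RNA were chosen after the result was seen. So were the tests of duckweed libraries 1 and 2 as sources and of other splits.

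In 5 of the 9 libraries, the 3 on duckweed and earthworm libraries 1 and 3, the most abundant transcript was CAFS_CommonC_G_016105. In 3 others it was CAFS_CommonC_G_068807, which averaged 63585 ± 6826 FPKM (SD, n = 3) on earthworm and 24703 ± 4996 FPKM (SD, n = 3) on duckweed and was at 96004 and 85565 FPKM in mixed-diet libraries 1 and 2. A gene with a nearby ID number, CAFS_CommonC_G_068809, averaged 27351 ± 5453 FPKM (SD, n = 3) on earthworm and 12430 ± 2544 FPKM (SD, n = 3) on duckweed. Both were lower in 3 of 3 duckweed libraries than in each earthworm library (two-sided exact permutation p = 0.1, the smallest possible), but neither passed the test across all genes (adjusted p = 1, limma, 9 libraries). Their log2 fold changes were -1.55 (SE 3.16) and -1.31 (SE 2.98) in that fit. Its spread was pooled over the diets and took in the library labelled earthworm+duckweed 3, at 41.7 and 18.2 FPKM. Without that library no gene passed in this comparison either (smallest adjusted p = 0.325, limma). Of the other 3 of the 5 most abundant genes, CAFS_CommonC_G_004942 went the other way, at 19626 to 24296 FPKM on duckweed and 15112 to 18308 FPKM on earthworm (exact permutation p = 0.1), but its libraries overlapped after scaling (exact permutation p = 0.3). CAFS_CommonC_G_016105 and CAFS_CommonC_G_009449 overlapped between the diets (exact permutation p = 1 and 0.8). Gene CAFS_CommonC_G_063277 was at 151.4, 153.3 and 1.22 FPKM on earthworm, at 98.1 and 17.7 FPKM in mixed-diet libraries 1 and 2 and at most 0.398 FPKM on duckweed.

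The library labelled earthworm+duckweed 3 stood apart from the other 8. Its total of 10631569 reads was not the lowest, and with the 500 most abundant genes of each library left out its highest Spearman correlation with another was 0.505, against 0.709 or more among the other 8, which argues against depth and against a few abundant genes. Mixed-diet libraries 1 and 2 correlated with the single-diet libraries at 0.905 on average, which argues against the mixed diet, and the highest correlation of the library labelled earthworm+duckweed 3 with a library of another diet was 0.52, against 0.851 or more among the other 8, which argues against its label having been swapped with that of another diet. Whether labels were swapped among the other 8 is open. Earthworm library 3 correlated better with duckweed libraries 1 and 2 (0.942 and 0.938) than with its own diet (0.876 and 0.893). Its share of reads in the 50 most abundant genes (42.1% against 34.6 to 38.6% on duckweed) went with its label. So did its CAFS_CommonC_G_068807 (55748 against 20600 to 30267 FPKM). Its CAFS_CommonC_G_063277, at 1.22 FPKM, was nearer to duckweed (at most 0.398 FPKM) than to earthworm libraries 1 and 2 (151.4 and 153.3 FPKM). These measures were picked after their values were seen, so they do not decide it. For the library labelled earthworm+duckweed 3, a sample of another tissue or origin with a trace of the RNA of the other 8 remains a candidate explanation. The 50 most abundant genes lay at a median of 0.145% of their mean in the other 8 (middle range 0.0931 to 0.235%), while 76.6% of the 1000 genes varying least among the 8 stayed within 4-fold. The library labelled earthworm+duckweed 3 had 26969 genes at 1 FPKM or more, against 15059 to 20051 in the other 8. Its most abundant gene, CAFS_CommonC_G_021668, was at 14939.8 FPKM, against 7.56 to 68.9 FPKM in the other 8. Without gene names the tissue could not be tested.

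Duckweed library 2 held the transcripts of duckweed library 3 at a floor. Over all genes at 10 FPKM or more in duckweed library 3, the 1st percentile of the ratio was 0.247. The next of the other 55 ordered pairs, duckweed library 2 over earthworm library 3, was at 0.203. For duckweed library 2 over duckweed library 3, 1 gene was under a ratio of 0.1, against 9 or more in each other pair. Duckweed library 2 was at a 1st percentile of 0.103 or more against each other library compared. A high 1st percentile was thus not particular to its pair with duckweed library 3. The duckweed diet as the cause would need such a floor in duckweed library 1 too, whose 1st percentile against duckweed library 3 was 0.0249. A source cannot raise a gene above its own level. Of the 58 genes particular to duckweed library 3, 58 were higher in duckweed library 2 than in duckweed library 1. Of the same 58, 57 were higher in duckweed library 3 than in duckweed library 2. These genes were chosen as high in duckweed library 3 and low in duckweed library 1, so both counts follow in part from that choice. They do not decide whether duckweed library 1 was a source for duckweed library 2, or duckweed library 2 for duckweed library 3. The 9 genes particular to duckweed library 2 were in duckweed library 3 at a median of 0.302 of their level. A test set first, a 1st percentile above 0.1, was met for both of these sources (0.17 and 0.101). As 17 of those 55 pairs met it, it decided nothing. RNA or reads of duckweed library 3 in duckweed library 2 may account for the pattern, although the margin over the next pair in the 1st percentile is small. Duckweed library 2 held the middle value of its diet in 53.8% of genes, where chance gives 33.3%. Each other library did so within its own diet in 16.5 to 43.9% of genes. A pooled sample or a milder form of a state of the same fish was not tested.

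A hypothesis was that consecutive ID numbers mark genes that vary together. Across 6756 pairs of tested genes with consecutive numbers, the log2 fold changes of duckweed against earthworm over 8 libraries correlated at 0.118, above the highest of 1000 shuffles at 0.0374. The correlation was 0.0341 at 2 steps, 0.0135 at 5 and 0.00113 at 10. Neighbouring genes that vary together between libraries, whether with diet or not, may account for this, as may copies or split gene models that share reads. The shuffles moved genes and not libraries, so they do not tie the correlation to diet. None of these explanations was tested.

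Other splits of the libraries were compared by the number of genes at an unadjusted p under 0.05 in fits of the groups compared. With 10 splits of 6 libraries, or of the 5 left without the library labelled earthworm+duckweed 3, no share under 0.05 is possible. Duckweed against earthworm gave 855 genes, the highest other split 3053, and 5 of the 10 splits gave as many. The mixed diet against earthworm gave 444, the highest other 1122, and 10 of 10 gave as many; without the library labelled earthworm+duckweed 3 it gave 1025, the highest other 1179, and 2 of 10 gave as many. Duckweed against the mixed diet gave 754, the highest other 1331, and 5 of 10 gave as many; without that library it gave 1358, the highest other 1762, and 3 of 10 gave as many. For the mixed-diet contrast, with 970 genes, 42 of 100 splits gave as many and the highest other gave 2746, and without that library, with 1294, 35 of 100 gave as many and the highest other gave 2317, so chance was not excluded. In duckweed against earthworm the highest other split gave several times the real count, and in the mixed-diet contrast without that library another split called 74 genes where the real one called 0, which may point to a structure of the samples other than diet; what it follows was not tested.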
